A study of Mus musculus with 5 samples.

How the data were processed

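Gene expression was measured in cells of the mouse kidney papilla, the innermost tip of the medulla. The mice carried a histone H2B-GFP fusion and received a doxycycline pulse before birth, followed by a chase until the animals were about 2 to 3 months old, per the labels' protocols. A cell that has divided little since the pulse keeps its GFP and is called label-retaining. Papillae were dispersed with collagenase, and live cells were sorted by FACS into GFP-positive (GFP+) and GFP-negative (GFP-) populations. RNA was amplified as cDNA by a global PCR protocol, SuperAmp, before Cy3 and Cy5 labelling, per the labels' protocols. Global PCR can change the relative amounts of transcripts from few cells, and each array carries that variation along with any biological one.

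The 5 arrays were 2-colour Agilent whole mouse genome arrays, each hybridised with GFP+ cDNA in Cy5 and GFP- cDNA in Cy3 of the same replicate, per the labels. No dye was swapped, per the labels, so a dye effect that is the same on every array is part of each ratio. The submitters' processing notes name Agilent Feature Extraction, and its version is not given in the sources used here. The deposited table of each array holds 1 value per probe for 2 channel intensities, their log10 ratio and a p-value, per the file headers. The deposited intensities are on a linear scale. The deposited log10 ratio equals that of the second intensity over the first within 0.001 for 89.1%, 84.0%, 78.3%, 82.5% and 87.0% of probes on replicates 1 to 5, and how the software set the others is not given in the sources used here. The deposited p-value belongs to that array alone, its error model is not given in the sources used here, and it was not used for any call. The authors' series matrix of log10 ratios equals the values of the single arrays within 0.001, except at 0, 1, 3, 1 and 1 probes on replicates 1 to 5. Its medians were -0.0224, 0.0009, 0, 0.0108 and 0.0517.

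Which dye the first intensity stands for is not given in the sources used here. The direction GFP+ over GFP- is therefore called likely. It rests on the convention that Agilent ratios are Cy5 over Cy3, on the labels that put GFP+ in Cy5, and on the way the deposited data of replicates 3 to 5 name the negative population before the positive one. Those of replicates 1 and 2 carry numbers only. If the direction is the opposite, all signs turn.

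The test design, the gene lists, the rule for named genes and the first 20 alternatives were fixed before the data were examined. The design had assumed scanner foreground and background signals and a normexp background correction. Those signals were not used here, so an offset of 50 was added to the deposited intensities before log2. Each array was then normalized by loess (span 0.3) with control probes at weight 0 and probes that the authors' software had marked left out (41, 14, 22, 22 and 21 on replicates 1 to 5). A probe counted as above background in a channel where its intensity reached 3 times that of the negative control probe. Probes above background in at least 1 channel on at least 3 of 5 arrays were tested. Of 41174 non-control probes, 33477 had 1 gene symbol, 45 had several and 7652 were unnamed here; 815 of the names came from a RefSeq accession. The brightest tested probe stood for a gene, which left 17424 genes, 6011 of them with a further tested probe.

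The log2 ratios of the 5 arrays were tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The array pairs both populations of a replicate. After removal of group means, the channels of 1 array correlated across genes at 0.146, 0.214, 0.289, 0.321 and 0.535 on replicates 1 to 5. A set of 30 gene lists with 590 entries, 584 of them on the array, was drawn up from textbook markers of cell types and from pathways. The cell types were not limited to those of the papilla, and the proximal tubule is among them. Lists were tested with camera (preset inter-gene correlation 0.01, and an estimated one) and with fry, each adjusted over the 30 lists. With an estimated correlation camera has only the degrees of freedom left by the arrays, so a failure to pass there is weak evidence. SD is the spread over arrays and SE is limma's. Values are log2 ratios unless stated otherwise. Where no array is named, the median of a list is that of its members' means over the arrays used. It can differ in sign from the list's medians on single arrays.

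Genes were named by rule. Since no gene passed on either side, the rule gave the 5 with the lowest unadjusted p on each side, leaving out clone, RIKEN and predicted names. It also gave at most 2 members of lowest unadjusted p per list and a fixed set of 21 genes. Of the 5 on the higher side, 1 is not reported here. One of those 21, Pdgfrb, lay below the filter and was not tested. The 87 named genes were above background on at least 2 arrays in each channel.

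On simulated log ratios of 17424 genes with the spreads of these arrays, the test recovered 0 of 50 genes changed 2-fold, 0 of 50 changed 4-fold, 0 of 50 changed 8-fold and 5 of 50 changed 16-fold. With the spreads multiplied by 0.25 it recovered 28, 45, 50 and 49 of 50, with 11 false calls. The principal cell list of 16 genes, raised 2-fold at the measured spreads, had a camera p of 0.00673 and an adjusted p of 0.202. The simulated genes were drawn independently, while the estimated inter-gene correlation of this list on the 5 arrays was 0.254. The recovery of lists may therefore be overstated. The simulation took the measured SD of each gene as its true one, and that SD includes any turn of replicate 1 against the others. The recovery of single genes may therefore be understated. The number of arrays and the spread between them limit the precision of all values.

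There were 24 alternatives, 20 planned and 4 added after seeing the data. They covered the offset, the normalization within and between arrays, the series matrix values, the filter on dim probes, the choice of probe, array weights, the variance prior, a fit of 10 unpaired channels, the arrays parted by the form of their deposited names (replicates 1 and 2 against 3 to 5), and leaving out each replicate. Slide and scan date are not given in the sources used here, so the planned slide block was not run, and normexp on scanner signals was not run either.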

Results

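The 5 arrays compared label-retaining GFP+ cells of the mouse kidney papilla with GFP- cells sorted from the same tissue, 5 biological replicates with 1 array each. The comparison asks which transcripts distinguish papilla cells that kept an embryonic nuclear label into adult life. Between 57.7% (replicate 4) and 75.3% (replicate 1) of probes were above background in the channel taken as GFP-, and between 59.4% (replicate 3) and 72.5% (replicate 5) in the channel taken as GFP+. Within an array the SD of the log2 ratio across genes was 2.17, 2.42, 2.13, 2.06 and 1.76 on replicates 1 to 5. Between 41.9% and 49.6% of genes differed at least 2-fold on a single array.

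No gene passed the test for a difference between GFP+ and GFP- cells across the 5 arrays. Of 17424 genes, limma called 0 at an adjusted p of 0.05, and the lowest adjusted p was 0.826. At an unadjusted p under 0.05 there were 867 genes, against 871 given by chance. A mean ratio of at least 2-fold was reached by 4501 genes, but the median SD over the arrays was 1.45 and none of these means passed the test against that spread. One sign on all 5 arrays was found for 1327 genes, 7.64% of those with 5 values, where chance gives 6.25%. With the sign of replicate 1 turned, an alternative chosen after seeing the data, there were 3116 such genes, against 1085 given by chance, and limma again called 0, with 2424 at an unadjusted p under 0.05. Without replicate 1 limma again called 0 genes, with 2008 at an unadjusted p under 0.05. The absence of calls does not exclude large differences, since at this spread the test recovered 5 of 50 simulated 16-fold changes.

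The genes reported here with the lowest unadjusted p on the higher side had ratios above 0 on all 5 arrays. They are values only, and each had an adjusted p of 0.826 in limma. The direction, GFP+ over GFP-, is likely rather than stated, and all signs turn if it is the opposite. The choice of genes also rests on replicate 1 as labelled: without it, of the genes given here for the higher side, only Sgcb (4.61 ± 1.21, SD, n = 4) was among the 10 of lowest unadjusted p. Sgcb, which encodes the membrane protein beta-sarcoglycan, had 4.86 ± 1.18 (SD, n = 5), with the GFP- channel above background on 2 of 5 arrays. Erlin2, which encodes a protein of the endoplasmic reticulum membrane, had 4.57 ± 1.60 (SD, n = 5). Txndc12, an endoplasmic reticulum thioredoxin, had 4.09 ± 1.44 (SD, n = 5). Tmem106c had 3.26 ± 1.22 (SD, n = 5). All tested probes of Sgcb and Erlin2 had the same sign (3 of 3 each), against 1 of 2 for Tmem106c.

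On the lower side, the lowest unadjusted p belonged to Trim56, Elp3, Msantd3, Ndufaf7 and Cdc25b, with ratios below 0 on all 5 arrays and an adjusted p of 0.826 in limma. Trim56, a ubiquitin ligase, had -3.15 ± 0.98 and Elp3, the catalytic subunit of Elongator, -2.76 ± 0.67 (SD, n = 5). Ndufaf7, an assembly factor of respiratory complex I, had a mean of -3.12, from -5.36 on replicate 2 to -1.47 on replicate 3. Msantd3, with the GFP+ channel above background on 2 of 5 arrays, had -2.29 ± 0.59, and Cdc25b, a phosphatase that activates cyclin-dependent kinases, had -2.11 ± 0.70 (SD, n = 5). All 3 tested probes of Cdc25b had the same sign. Without replicate 1, none of these 5 genes was among the 10 of lowest unadjusted p on the lower side.

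Among the genes named whatever their values, Zfyve27 and Cxcl12 had one sign on all 5 arrays, and so did Upk3a. Zfyve27 encodes protrudin, a protein of membrane trafficking into cell protrusions. Its ratio was 2.61 ± 2.02 (SD, n = 5), from 0.19 on replicate 1 to 5.04 on replicate 2, with an unadjusted p of 0.0140 and an adjusted p of 0.826 in limma. The other probes of Zfyve27 did not follow, and 1 of 3 tested probes had the sign of the mean. Zfyve27 was later used for lineage tracing by the same investigators, so its value here is not independent evidence. Cxcl12, a chemokine, had -2.20 ± 1.68 (SD, n = 5; unadjusted p 0.0167, adjusted p 0.826, limma), and its receptor Cxcr4 had 1.23 ± 2.21 (SD, n = 5), with 5.05 on replicate 3 and -0.33 to 0.88 on the others. The uroplakin gene Upk3a had 0.72 ± 0.48 (SD, n = 5). Among progenitor markers, Nes had -0.04 ± 0.70, Lgr5 -0.06 ± 0.79, Cd24a 0.29 ± 0.92, Sox9 0.13 ± 2.11 and Prom1 -3.20 ± 5.06 (SD, n = 5). Lgr5 was above background on 3 arrays in the GFP+ and 2 in the GFP- channel, and Prom1 on 3 and 4. From the list of stem and progenitor markers, 3 of 25 genes had one sign on all 5 arrays, among them Cited1 with -1.60 ± 1.12 and Itga6 with 1.92 ± 1.36 (SD, n = 5; unadjusted p 0.0228 and 0.0167, adjusted p 0.826, limma). Of 2 tested Itga6 probes 1 had this sign. The proliferation marker Mki67 had -0.03 ± 3.67, and the cell cycle inhibitors Cdkn1a and Cdkn1c had 0.93 ± 2.10 and 0.13 ± 1.12 (SD, n = 5). Without replicate 1, Prom1 had -4.92 ± 3.79, Sox9 -0.33 ± 2.13, Mki67 0.70 ± 3.79, Cdkn1a 1.65 ± 1.54 and Cdkn1c -0.35 ± 0.40 (SD, n = 4), with adjusted p of at least 0.361 in limma. The values for Cdh1, Pecam1 and Ptprc, which mark epithelium, endothelium and leukocytes, were -0.46 ± 0.86, -0.67 ± 1.12 and -0.75 ± 2.37 (SD, n = 5). Without replicate 1 they were -0.779 ± 0.554, -1.038 ± 0.887 and -1.335 ± 2.291 (SD, n = 4), with adjusted p of at least 0.469 in limma.

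**Figure D1:**
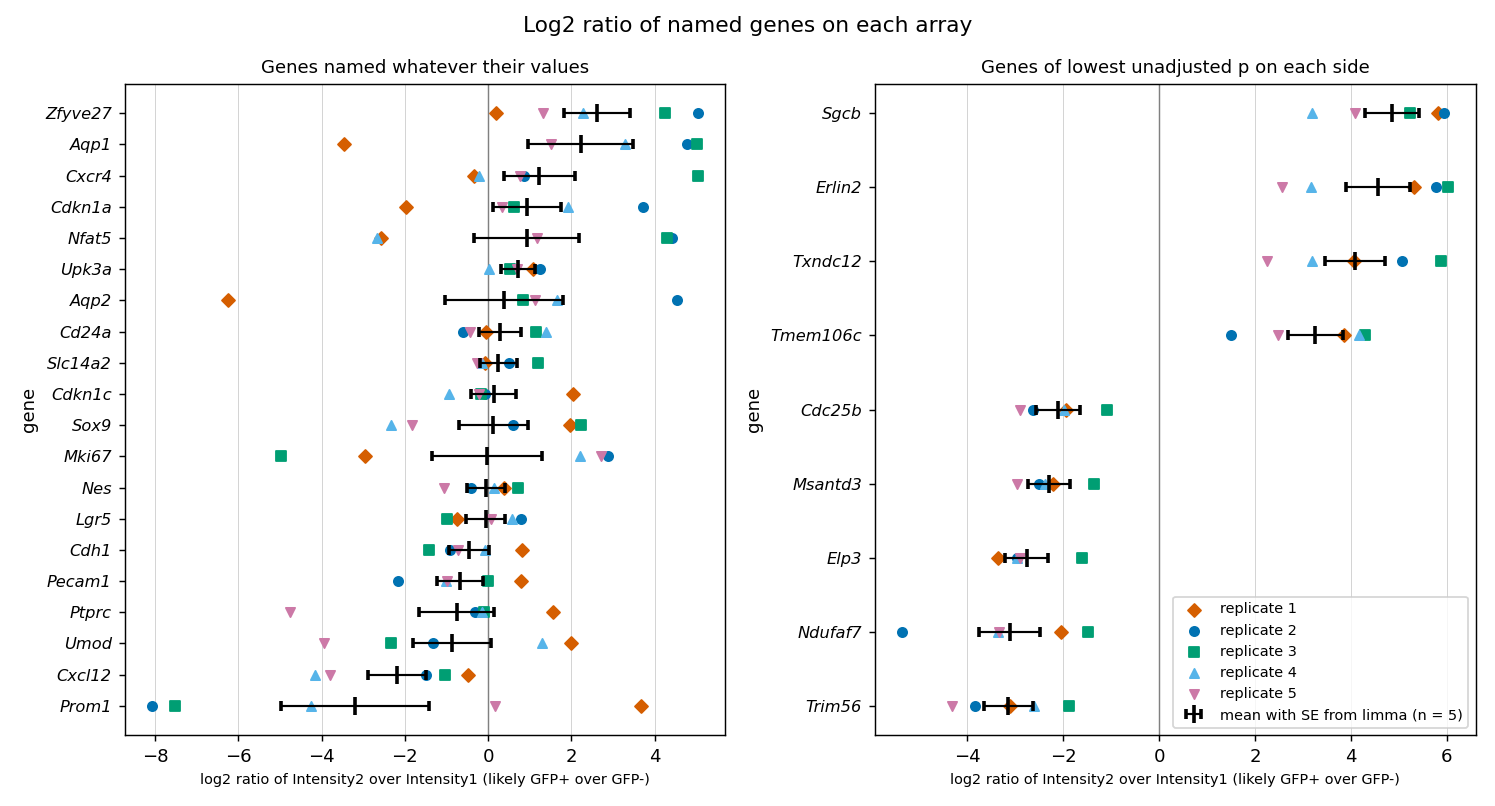
Log2 ratio of named genes on each of 5 arrays (coloured points), with the mean and limma's SE (black). On the left are genes named whatever their values, where Aqp2 runs from -6.24 on replicate 1 to 4.53 on replicate 2, and on the right genes of lowest unadjusted p on each side; no gene passed an adjusted p of 0.05.

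Some markers of the tubule segments of the papilla had large ratios that turned between replicate 1 and the others. On replicates 2 to 5 one sign was found for 4 of 16 principal cell, 5 of 12 intercalated cell and, with 5 above 0 and 1 below, some of the 14 thin limb genes, and 4, 5 and 5 of these had the opposite sign on replicate 1. Aqp2, the vasopressin-regulated water channel of collecting duct principal cells, had -6.24 on replicate 1 and 0.83 to 4.53 on replicates 2 to 5. Aqp1, the water channel of the thin descending limb, had -3.45 on replicate 1 and 3.65 ± 1.62 (SD, n = 4) on the others. Slc4a1, the anion exchanger of acid-secreting intercalated cells, had -6.27 on replicate 1 and 3.10 to 6.79 on the others. Of the 16 principal cell, 12 intercalated cell and 14 thin limb genes tested, limma called 0, over all genes tested and adjusted over the list alone, with 0, 0 and 1 at an unadjusted p under 0.05. Their camera p values were 0.354, 0.293 and 0.105. The osmolyte and tonicity list, with 0 of 13 members called in limma and 0 at an unadjusted p under 0.05, had a median of -2.02 on replicate 1 and 0.51 to 1.75 on the others (camera p 0.167), and shares Aqp1, Slc14a2, Cryab and Akr1b3 with the thin limb list. Nfat5, the regulator of the osmotic response, had 0.93 ± 3.49 (1.80 ± 3.34 without replicate 1, SD, n = 4), and the urea transporter gene Slc14a2 0.25 ± 0.61 (SD, n = 5). Oxidative phosphorylation genes, with 0 of 36 called in limma and 2 at an unadjusted p under 0.05, had a median of 1.97 on replicate 1, and medians of -0.58, -0.30 and -0.36 on replicates 2, 3 and 5, with that of replicate 4 also below 0 (camera p 0.361).

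Without replicate 1, 4 lists passed camera's preset correlation. The intercalated cell list was higher (adjusted p 0.0202), as were the thin limb (adjusted p 0.0202) and the osmolyte lists (adjusted p 0.0267), and oxidative phosphorylation was lower (adjusted p 0.0410). With an estimated correlation each of the 4 had an adjusted p of 0.568 in camera. The estimates were -0.074 (intercalated), 0.195 (thin limb), 0.014 (osmolyte) and -0.016 (oxidative phosphorylation). For the intercalated and oxidative phosphorylation lists the estimate lay below the preset 0.01, so a stronger correlation does not account for their loss. The few degrees of freedom of this setting limit what can pass. The principal cell list had an adjusted p of 0.0642 with the preset correlation. With the sign of replicate 1 turned it passed along with these 4, and with an estimated correlation no list then passed (lowest adjusted p 0.393). In fry, which tests whether members move one way, only the intercalated list passed without replicate 1 (adjusted p 0.0106). With all 5 arrays as labelled 0 lists passed fry, with replicate 1 turned also 0, and with a dye term added to that 1. The dye term keeps the dye effect in one direction on all 5 arrays, as if replicate 1 were a dye swap. The labels name no swap, and control probes turned on replicate 1 as well, so that pass is weak evidence. In limma 0 members of these lists passed over all genes tested. Adjusted over the list alone, which does not correct for the number of lists, 15 members summed over 7 lists passed without replicate 1. All 15 had the opposite sign on replicate 1. They were 5 thin limb genes (lowest adjusted p 0.0111), 2 intercalated cell genes (0.00975), 2 osmolyte genes (0.0205), which are also in the thin limb list, 2 urothelial genes (0.0472), 1 erythroid gene (0.0223), 2 TGF-beta and BMP genes (0.0390) and 1 interferon gene (0.0230).

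**Figure D2:**
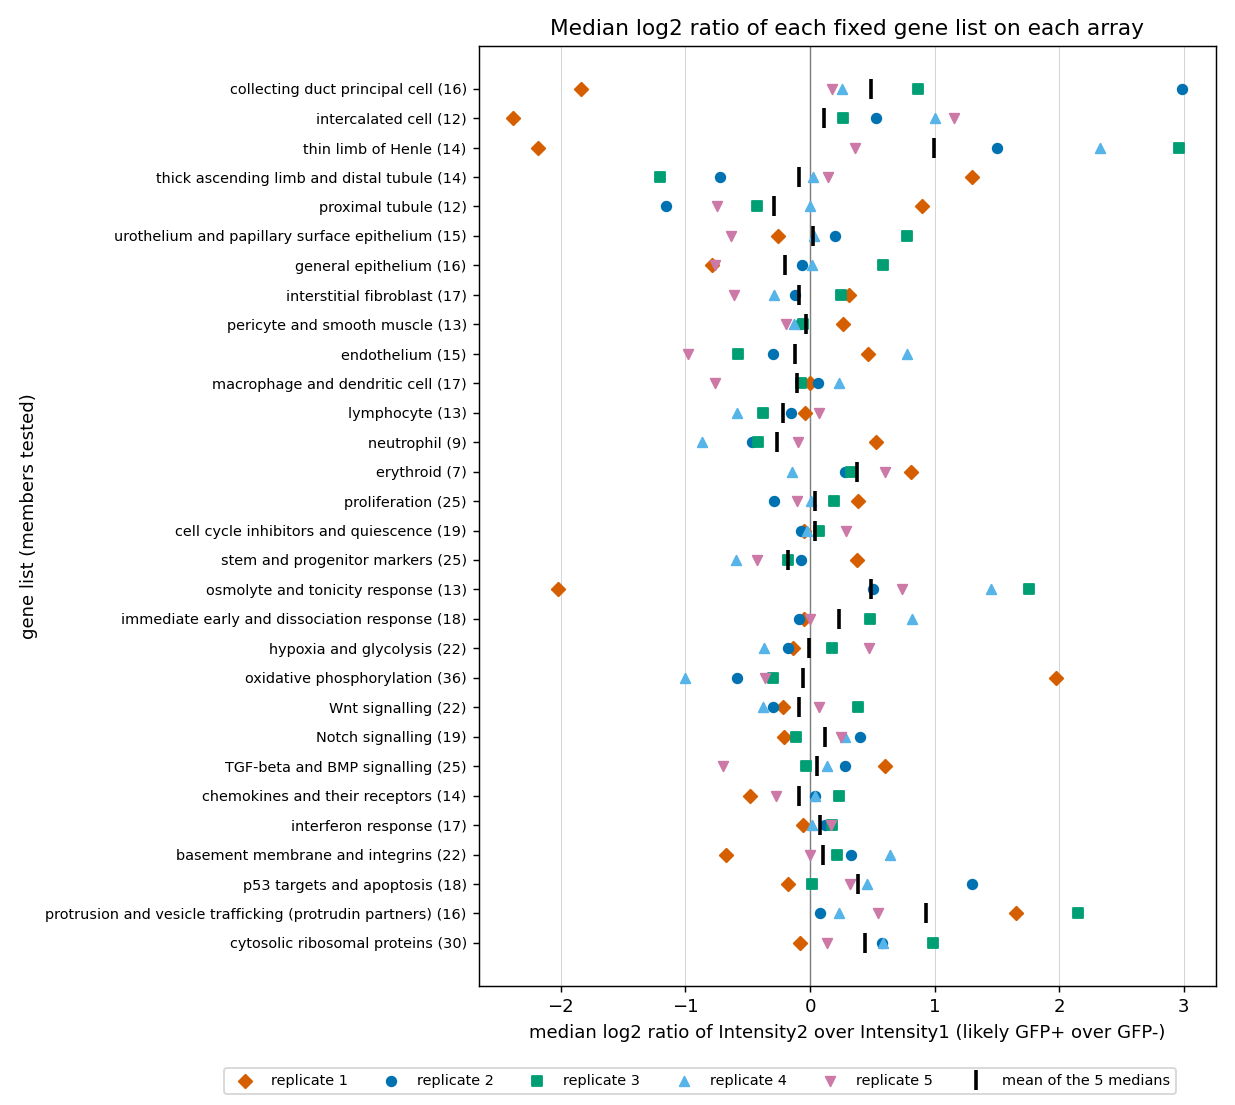
Median log2 ratio of each of 30 gene lists on each of 5 arrays, with the mean of the 5 medians in black and the number of members tested in brackets. In 12 lists the medians of replicates 2 to 5 lie on one side of 0 and that of replicate 1 on the other, among them the intercalated cell list (-2.39 against 0.26 to 1.15).

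Of the lists for other cell types, none passed camera with all 5 arrays. Summed over the 30 lists, limma called 0 of 531 members over all genes tested and 1 adjusted over the list alone, with 28 at an unadjusted p under 0.05. The last count is close to what chance gives. The thick ascending limb list had 5 of 14 means above 0 and a median of -0.28 (camera p 0.290), with Umod at -0.86 ± 2.48 (SD, n = 5). Without replicate 1 it had 3 of 14 above 0 and a median of -0.70 (camera p 0.157, adjusted p 0.339), with Umod at -1.575 ± 2.19 (SD, n = 4). The proximal tubule list had 3 of 12 above 0 and a median of -0.31 (camera p 0.238), and without replicate 1 a median of -0.66 (camera p 0.0236, adjusted p 0.111). The urothelial list, which includes the papillary surface epithelium, had 8 of 15 above 0 and a median of 0.11 (camera p 0.798). The fibroblast list had 7 of 17 above 0 (median -0.13, camera p 0.667), the pericyte list 7 of 13 (median 0.27, camera p 0.475) and the endothelial list 5 of 15 (median -0.31, camera p 0.196). For the pericyte list the mean of the 5 array medians was -0.04. The leukocyte lists had medians of member means below 0 and did not pass. On single arrays the median of the macrophage and dendritic list lay on both sides of 0, from -0.76 on replicate 5 to 0.23 on replicate 4. Lymphocyte genes had 2 of 13 means above 0 and a median of -0.39 (camera p 0.0253, adjusted p 0.380; fry adjusted p 0.114; camera p 0.167 without replicate 1), macrophage and dendritic genes 5 of 17 (median -0.37, camera p 0.112) and neutrophil genes 2 of 9 (median -0.30, camera p 0.156). Erythroid genes had 5 of 7 above 0, with a median of 0.27, a mean of -0.19, and a camera p of 0.998 on the lower side. Without replicate 1, 2 urothelial genes and 1 erythroid gene passed adjusted over the list alone (lowest adjusted p 0.0472 and 0.0223 in limma).

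With all 5 arrays, the general epithelium list held the only gene to pass adjusted over the list alone. Krt7, a keratin of simple epithelia, had -1.82 ± 0.24 (SD, n = 5) and lay below 0 on all 5 arrays. Its adjusted p in limma was 0.0428 over the list alone and 0.826 over all genes tested. Only 1 of its 2 tested probes had this sign, and with the mean of both probes the ratio was -0.79 (limma adjusted p 0.714 over the list alone). Leaving out any 1 replicate took the adjusted p over the list alone to between 0.0765 and 0.169 in limma. The whole list had a median of 0.36, a mean of -0.18, and a camera p of 0.543 on the lower side. The mean of its 5 array medians was -0.20.

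The lists for quiescence, progenitor and signalling genes held no called member with all 5 arrays, over all genes tested or adjusted over the list alone. Without replicate 1, 2 TGF-beta and BMP genes and 1 interferon gene passed adjusted over the list alone (lowest adjusted p 0.0390 and 0.0230 in limma). The proliferation list had 11 of 25 means above 0 (median -0.12, mean -0.02, camera p 0.771 on the higher side) and the list of cell cycle inhibitors and quiescence genes 9 of 19 (median -0.01, mean 0.19, camera p 0.584 on the higher side). Without replicate 1 the proliferation list had 13 of 25 above 0 (median 0.17, camera p 0.961 on the lower side). Stem and progenitor markers had 10 of 25 above 0 (median -0.06, camera p 0.368). The Wnt, Notch, and TGF-beta and BMP lists had medians of -0.07, 0.36 and 0.29 (camera p 0.577, 0.428 and 0.711), and the last had a mean of -0.06 with camera on the higher side. Chemokine and interferon genes had medians of -0.43 and 0.04 (camera p 0.332 and 0.515). Without replicate 1 the Notch and chemokine medians were 0.1475 and -0.0040 (camera p 0.157 and 0.422). The list of protrudin partners and vesicle trafficking, which holds Zfyve27, had 11 of 16 above 0, a median of 0.46, a camera p of 0.0194 and an adjusted p of 0.380 (camera p 0.169 without replicate 1). Basement membrane and integrin genes had 15 of 22 above 0 (median 0.26, camera p 0.567), with Itgav at -2.24 ± 0.98 and Lamb2 at -3.63 ± 2.89 (SD, n = 5). The p53 list had 12 of 18 above 0 (median 0.43, camera p 0.105), and without replicate 1 a median of 0.59 (camera p 0.0259, adjusted p 0.111). Of the other lists, ribosomal protein genes had 20 of 30 above 0 (median 0.47, camera p 0.0779), immediate early genes 12 of 18 (median 0.27, camera p 0.609), and hypoxia and glycolysis genes 11 of 22 (median -0.08, camera p 0.792). With an estimated correlation the adjusted p was at least 0.849 for all 30 lists.

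The arrays shared little with one another across genes, which are not independent replicates. Pearson correlations of the log2 ratios were between 0.0496 and 0.203 among replicates 2 to 5, and between -0.155 and -0.0604 for replicate 1 with each of them. Over all probes with the deposited ratios, the corresponding ranges were 0.0595 to 0.217 and -0.169 to -0.0580. The direction given by the labels was kept for replicate 1. Different probes of 1 gene also agreed weakly within an array, with correlations across 6011 genes of 0.205, 0.184, 0.215, 0.172 and 0.144 on replicates 1 to 5.

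**Figure D3:**
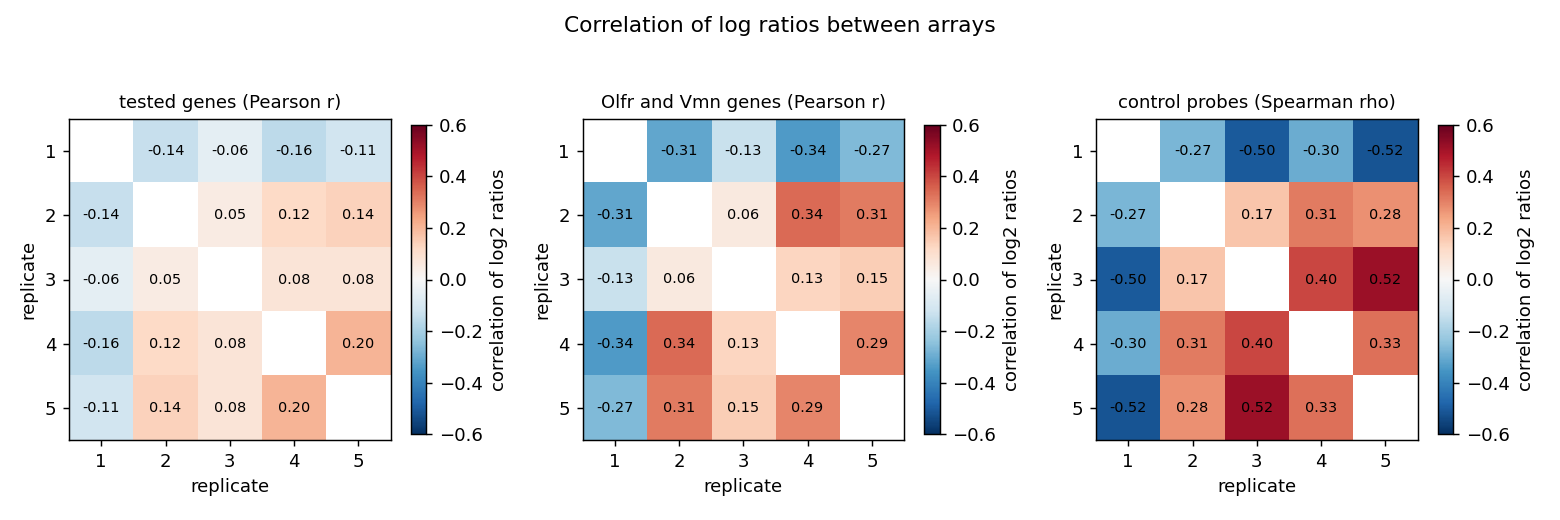
Correlation of log ratios between each pair of the 5 arrays, over 17424 tested genes (left), over odorant (Olfr) and vomeronasal (Vmn) receptor genes (middle) and over 93 control probes (right). In all 3 panels replicate 1 correlates below 0 with the other arrays, with medians of -0.127, -0.290 and -0.401.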

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

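The tests of sign patterns, of the signal on replicate 1 and of control probes were chosen after the results were seen. The values listed first are those of 1 array that lay far from the other 4. Chance gives such a value in about 1 of 20 groups, and 12 were found among 87 genes, 30 lists and 5 array measures.

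On replicate 1 the log2 ratio lay apart for Slc4a1 (-6.27), Cryab (-1.79), Fas (-0.77), Retnlg (1.96) and Gadd45g (4.86). The medians of the intercalated cell list (-2.39) and of the oxidative phosphorylation list (1.97) on replicate 1 also lay apart, as did its share of probes above background in the channel taken as GFP- (75.3%). On replicate 3 the ratios of Cxcr4 (5.05), Avpr2 (3.60) and Elp3 (-1.60) lay apart, and on replicate 4 that of Ndufs1 (-1.79).

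Spike-in probes for an adenovirus transcript, which were not part of the comparison, gave signal: 7 of 10 lay above 3 times the negative control in both channels on all 5 arrays. The brightest had intensities of 8211 and 29411 in the channels taken as GFP- and GFP+ on replicate 1. On replicates 2 to 5 the order was the opposite, with 35635 to 102110 in the first channel and 5060 to 19341 in the second.

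Replicate 1 ran against replicates 2 to 5. Genes picked on replicates 2 to 5 alone and outside the fixed lists had the opposite sign on replicate 1 in a share of 0.751. The 95% Wilson interval was 0.731 to 0.771 over 1794 genes, and it treats genes of 1 array as independent, which they are not. Genes picked on 3 of those arrays had the opposite sign on replicate 1 in a share of 0.723 to 0.761. On the array left out they had the same sign in a share of 0.688 to 0.780. Control probes turned as well (median Spearman correlation -0.401 with replicate 1, 0.321 among the others). The turned genes and the turned control probes both go with exchanged channels on replicate 1. The share of turned genes, however, follows from the correlations below 0 of replicate 1 with the other arrays. Any cause of those correlations would give it, so it is no separate evidence for exchanged channels. The correlation between probes of 1 gene was 0.205 on replicate 1 and 0.144 to 0.215 on the others. This argues against noisier single probes on replicate 1. Noise from sorting or global PCR would be shared by both probes of a gene, so this correlation cannot address it. The array weight was 0.486 on replicate 1 and 1.05 to 1.40 on the others, but running against the others lowers it too. A different mix of kidney cell types in the sorts of replicate 1 cannot be told apart for these genes. The share outside the cell type lists was 0.750, but the lists took out only 30 genes, and a changed mix would turn unlisted genes too. A changed mix would not turn the array's own control probes, whose Spearman correlations with replicate 1 lay between -0.5195 and -0.275. The brightest adenovirus spike-in probe turned too, and the order of the channels for the other spike-in probes is not given here. For the control probes these correlations argue against a changed mix. Odorant and vomeronasal receptor genes turned too, with correlations with replicate 1 between -0.342 and -0.132. They were assumed, without a test, not to differ between kidney populations. Under that assumption their values also argue against a changed mix, for the receptor genes alone. For the other genes the question stays open. A biological difference between the animals of replicate 1 and the others was not tested.

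The labelled direction of the arrays was compared with the other sign patterns. The labels gave 867 genes at an unadjusted p under 0.05 in limma, and 3 of the 16 sign patterns of the 5 arrays gave as many, the labelled one included. The highest other count was 2424, with replicate 1 alone turned. That count follows from the correlations below 0 of replicate 1 with the other arrays and is no separate evidence for a cause. With 16 patterns no share under 0.05 can be had. Patterns with replicate 1 and 1 further array turned gave up to 8 lists past camera's preset correlation, more than the 5 with replicate 1 alone turned. With an estimated correlation 0 lists passed in camera under any of the 16 patterns (lowest adjusted p 0.347), a setting whose few degrees of freedom let little pass.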

How the results depend on the processing

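The alternatives with replicate 1 turned, with all probes, and with dim intensities raised were chosen after seeing the data. The one with a dye term treats replicate 1 as a dye swap, with the dye effect in one direction on all 5 arrays. The labels name no swap, and the control probes turned too, so its counts are weak evidence. Limma called 0 genes under all 24 alternatives, with a lowest adjusted p of 0.138 to 1.00, and 0 also with the added demand of a 2-fold change. The count at an unadjusted p under 0.05 (867) was 1578 with array weights, 1568 with replicates 3 to 5 only, 497 with replicates 1 and 2 only, 1433 with all tested probes, 550 with both channels above background on all 5 arrays, 2424 with replicate 1 turned, 2456 with replicate 1 turned and a dye term, and 596 to 2008 when each replicate was left out, the highest without replicate 1. All tested probes were 29814 and the stricter filter left 11354 genes, which moves both counts; for the others the cause was not tested. The fit of 10 unpaired channels, with no replicate block, gave 583 such genes and 0 calls, and the pairing changed no call over all genes, but Krt7 did not pass adjusted over the list alone without it (adjusted p 0.624). The number of lists past camera's preset correlation (0) was 4 with replicates 3 to 5 only, 5 with replicate 1 turned, 6 with replicate 1 turned and a dye term, and 0 to 4 when each replicate was left out; with an estimated correlation it was 0 under each of these. Krt7 missed the threshold adjusted over the list alone in 18 of 23 alternatives; its ratio (-1.82) lay between -1.96 and -1.76 in 20 of them, and was -0.79 with the mean of probes, -1.09 with replicate 1 turned and 0.0087 with replicate 1 turned and a dye term. The median correlation of replicate 1 with the other arrays stayed between -0.145 and -0.121 over the normalizations, filters and probe choices tried. The slide block and normexp were not run. Signal over background limits dim genes: 17424 of 20052 genes passed the filter, and the others were not tested.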

Other observations

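The test of receptor genes and those of further probes were set down before their results were seen, and the genes of the next paragraph, the limit to probes above background throughout, and the demand that a whole interval lie beyond a bound were chosen after values were seen.

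Several genes had close values on replicates 2 to 5 and the opposite sign on replicate 1, all with a limma adjusted p of 0.322 without replicate 1. Il6st, the shared receptor subunit of interleukin-6 family cytokines, had 4.17 ± 0.38 (SD, n = 4) and -2.07 on replicate 1. The nuclear RNA Neat1 had 3.69 ± 0.61 (SD, n = 4) and -3.96 on replicate 1, and Cdh2, which encodes N-cadherin, 2.67 ± 0.22 (SD, n = 4) and -1.12 on replicate 1. Cox7a2, a subunit of cytochrome c oxidase, had -2.33 ± 0.25 (SD, n = 4) and 3.59 on replicate 1. Rapgef4 had -4.13 ± 1.03 (SD, n = 4) and 4.11 on replicate 1. The odorant receptor gene Olfr356 had -3.20 ± 0.56 (SD, n = 4) and 2.29 on replicate 1.

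A hypothesis is that part of what replicates 2 to 5 share may be an effect of dye or probe rather than of mRNA. Odorant and vomeronasal receptor genes were assumed, without a test, not to differ between kidney populations. Over 796 of them the median correlation among replicates 2 to 5 was 0.220, against 0.0965 for other genes. For 1000 random sets matched on brightness it was 0.0695 to 0.173 (central 95%). The sets were matched on brightness alone, so similar probe sequences within the receptor families were not accounted for. They turned on replicate 1 too, with a median correlation of -0.290. This holds for the receptor genes and says nothing of the tubule genes, and receptor genes made up 3.64% of the genes of one sign and unadjusted p under 0.05 on replicates 2 to 5, against 4.57% of all tested genes. Without a dye swap, dye and GFP status share each array.

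Second probes left open whether the differences of single genes are of this kind. Of 233 genes with one sign on all 5 arrays and an unadjusted p under 0.05, a share of 0.575 of second probes had the sign of the first (95% Wilson interval 0.511 to 0.637). Of 506 genes that turned between replicate 1 and the others the share was 0.538 (0.494 to 0.581), and it was 0.613 (0.543 to 0.679) for the 194 with both probes above background throughout. With the same limit, the share for the genes of one sign was 0.561 (0.441 to 0.674, 66 genes). Over all genes with further probes it was 0.531. A share of at most 0.55 had been set as the sign of a probe effect and one over 0.65 as its absence. Although 0.538 lies under the first, each of these 4 intervals spans 0.55, so the explanations cannot be told apart for these genes. The intervals treat genes as independent, and wider ones would span 0.55 as well. A second probe outside the stretch copied by the amplification could also fail to follow.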
